A study of Mus musculus with 10 samples.

How the data were processed

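RNA sequencing had been carried out on 10 mouse samples in 5 groups of 2 libraries each: lung of wild-type mice, Kras lung tumours, mNSD2;Kras lung tumours, and primary cells derived from mNSD2;Kras tumours that were labelled sgControl or sgNSD2. Per the labels, total RNA was extracted with Trizol, and libraries were constructed and sequenced at BGI. The authors' processing notes name HISAT2 version 2.2.1, featureCounts and the mouse genome build mm10. Neither the gene annotation nor the strand setting of the counting was given in the sources used here, so reads of genes that overlap on opposite strands could not be told apart. Each deposited file held raw read counts for 25277 gene symbols. The values were whole numbers, and they were used without any earlier scaling. Of the symbols, 98.0% were found in the GENCODE M21 annotation, which gave the gene positions on GRCm38.

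Library totals ran from 18234438 to 20798153 counts. Intervals and lower bounds given for genes with few counts cover counting error only, since reads copied during amplification are not independent molecules. The intervals are 95% exact binomial intervals of the summed counts scaled by library size. Where a group had 0 counts, the fold was computed against a floor of 3 counts per library and is given as a lower bound.

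Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total count 15), which left 15824 genes in a fit of the 6 tissue libraries and 12264 genes in a fit of the 4 cell libraries. Libraries were scaled by TMM. Dispersions were estimated with estimateDisp, and each comparison was tested with the quasi-likelihood F-test of glmQLFit in its default settings, two-sided. P values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and a gene was called at an adjusted p under 0.05. The comparisons were Kras tumour against wild-type lung, mNSD2;Kras tumour against wild-type lung, mNSD2;Kras tumour against Kras tumour, and sgNSD2 against sgControl cells. Fold changes are given on the log2 scale with a standard error derived from the F statistic. Levels are TMM-scaled CPM (counts scaled to a common library size), with the SD of the 2 libraries. The scaling was done separately for tissue and cell libraries, so gene levels cannot be compared between tissues and cells. With 2 libraries against 2, chance alone separates the groups without overlap in 33.3% of genes.

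Before the data were examined, 35 gene lists were written, covering the cell types of lung and tumour, signalling and stress pathways, the cell cycle, antigen presentation, chromatin enzymes and gene classes that reflect RNA handling. A list was tested when at least 3 of its genes had passed the filter. The test was camera with its preset correlation of 0.01, which compares a list's genes with the other genes, and P values were adjusted over the lists of a comparison. Camera with a correlation estimated from the data and fry, which asks whether the genes of a list move one way on balance, were run beside it. With an estimated correlation camera tests on the residual degrees of freedom, 3 in the tissue fit and 2 in the cell fit. It therefore had little power after adjustment over the lists, and a list that it did not call is not thereby shown to be unchanged. Further lists, 6 in number, were written after the data had been seen. List levels per library are means of log2(CPM + 1) over genes with any count, with all 10 libraries scaled together.

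The genes named in the text were set by a rule written in advance. Nsd2 and Kras are given in every sample. In each comparison the rule takes the 8 genes with the largest rise and the 8 with the largest fall among called genes whose groups do not overlap and whose mean in the higher group is at least 5 CPM. It leaves out predicted and clone-named genes, immunoglobulin and T cell receptor segments, and pseudogenes. Of each list described, it takes up to 4 members with the smallest adjusted p among called genes and fills the remaining places with the members of highest mean CPM. Genes named outside this rule are said to have been chosen after their values were seen.

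The pipeline was tested on simulated data made from the fitted means and dispersions, with 100 genes changed by a log2 fold change of 1 and 100 by 2. In the order of the comparisons above, 40%, 27%, 35% and 12% of the smaller changes and 84%, 81%, 81% and 72% of the larger changes were recovered, with 20, 10, 8 and 7 false calls among the unchanged genes. In each comparison, from a single simulated draw, false calls made up a larger share of the calls than the threshold of 0.05 aims at. With camera at its preset correlation and no adjustment, a planted list of 20 genes passed the threshold of 0.05 in all 4 comparisons. An unchanged list of 20 genes passed it in 1, mNSD2;Kras tumour against Kras tumour.

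Alternatives set in advance were scaling by DESeq2 size factors or upper-quartile factors, no filter on low counts, a filter at 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), a robust prior, a fit of the compared groups alone, a fit of all 10 libraries, replicate number as a block, a test against a log2 fold change of 1, and leaving out each library in turn. Alternatives added later were the newer quasi-likelihood option of edgeR, an offset that removes each library's trend on transcript GC content and length, a term for sex in the tissue fit, leaving out X- and Y-linked genes, crossed pairing of the cell libraries, leaving out genes of cardiac muscle and others over 4 times higher in one sgNSD2 library, and upper-quartile factors for the gene lists. The groups hold too few libraries for tests of single outlying samples or of regrouped samples. No library and no measured gene beyond the filters was left out of the comparisons.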

Results

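Transcripts were counted by RNA sequencing in 10 mouse libraries. They came from lung of wild-type mice, from lung tumours labelled Kras, from lung tumours labelled mNSD2;Kras, and from primary cells of mNSD2;Kras tumours labelled sgControl (a control guide RNA) or sgNSD2 (a guide RNA against Nsd2, the gene of a histone H3 lysine methyltransferase). Each of the 5 groups had 2 libraries. Total counts were 18234438 and 18989761 in wild-type lung, 19029109 and 19003753 in Kras tumours, 19081611 and 18672164 in mNSD2;Kras tumours, 19787914 and 20796929 in sgControl cells, and 20798153 and 20722556 in sgNSD2 cells. The labels do not say whether replicates were separate animals or cultures, so p values measure only the spread between these libraries. Among genes above 1 CPM, the share that differed more than 2-fold between replicates was 0.214% in Kras tumours, 0.835% in sgNSD2 cells, 3.52% in wild-type lung, 4.24% in mNSD2;Kras tumours and 12.8% in sgControl cells. Xist, which is transcribed from the inactive X chromosome, stood at 464 and 441 CPM in wild-type lung and 512 CPM in mNSD2;Kras tumour 2. The Y-linked gene Ddx3y stood at 72.6 and 75.9 CPM in Kras tumours and 74.5 CPM in mNSD2;Kras tumour 1, so sex differed completely between wild-type lung and Kras tumours. Both sex-linked genes were chosen after their values were seen.

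Nsd2 mRNA (chromosome 5, 33820725 to 33897975, plus strand) was higher in both tumour groups than in wild-type lung. It measured 43.6 and 43.7 CPM in wild-type lung, 76.9 and 71.8 CPM in Kras tumours, and 83.9 and 65.0 CPM in mNSD2;Kras tumours. Kras tumours exceeded wild-type lung by a log2 fold change of 0.77 ± 0.14 (SE, n = 2 per group, adjusted p = 0.0373), a rise of 1.70-fold, and mNSD2;Kras tumours by 1.71-fold (adjusted p = 0.019). With a term for sex, which differed completely between wild-type lung and Kras tumours, the log2 fold changes were 0.40 (adjusted p = 0.184) and 0.575 (adjusted p = 0.018). That term rests on the difference between mNSD2;Kras tumours 1 and 2 alone. These values therefore do not show what part of a rise is due to sex. The first call ended without Kras tumour 1 or 2 (adjusted p = 0.351 and 0.208) and without wild-type lung 1 or 2 (0.119 and 0.174), and the second without Kras tumour 1 or 2 (0.07 and 0.0716) and without wild-type lung 1 or 2 (0.0749 and 0.0999). The 2 tumour groups differed by a log2 fold change of 0.00 ± 0.14 (adjusted p = 0.997), which was -0.19 without mNSD2;Kras tumour 1 and 0.17 without tumour 2. In the cells, no fall of Nsd2 mRNA was called under the sgNSD2 label, although the titles of these libraries carry the tag NSD2_KD. It measured 101 and 107 CPM there and 118 and 78.7 CPM in sgControl cells, a log2 fold change of 0.08 ± 0.31 (adjusted p = 0.898). The sign turned without sgControl 2 (-0.17) and with the GC and length offset (-0.28), and the value was 0.31 without sgControl 1 (adjusted p over the alternatives from 0.146 to 1). A guide RNA that disrupts a gene need not lower its mRNA, and the counts give no measure of NSD2 protein. The cell groups are therefore described by their labels.

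Kras mRNA (chromosome 6, 145216699 to 145250239, minus strand) showed no called difference in any comparison when all libraries were used. It measured 103 and 129 CPM in wild-type lung, 119 and 119 CPM in Kras tumours, 111 and 103 CPM in mNSD2;Kras tumours, 26.5 and 12.4 CPM in sgControl cells and 21.5 and 25.1 CPM in sgNSD2 cells. The log2 fold changes were 0.03 for Kras tumours against wild-type lung (adjusted p = 0.903), -0.12 for mNSD2;Kras tumours against wild-type lung (adjusted p = 0.53), -0.15 between the tumour groups (adjusted p = 0.636) and 0.26 in the cells (adjusted p = 0.745). In the cells it was called higher without sgControl 1 (0.81, adjusted p = 0.00404) and was -0.18 without sgControl 2 (adjusted p = 0.663).

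**Figure D1:**
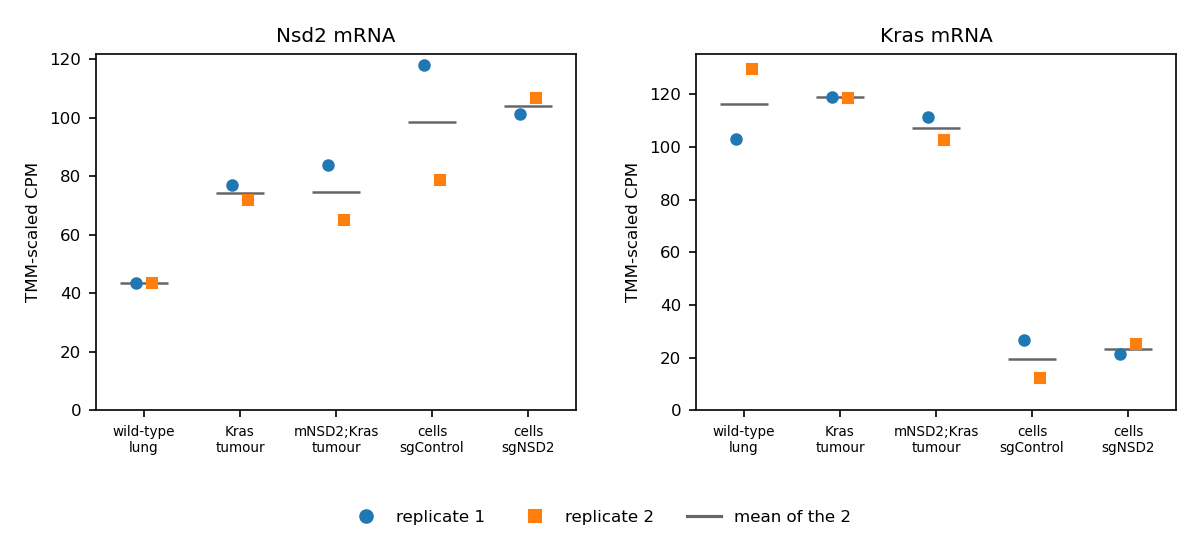
Nsd2 and Kras mRNA in TMM-scaled CPM (vertical axes) in the 5 groups (horizontal axes), with circles for replicate 1, squares for replicate 2 and lines for their mean. Tissue and cell libraries were scaled separately, so levels cannot be compared between tissues and cells. Nsd2 lies at 43.6 and 43.7 CPM in wild-type lung and between 65.0 and 83.9 CPM in the 4 tumour libraries, and the 2 libraries labelled sgNSD2 lie between those labelled sgControl.

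The first comparison asked how the transcriptome of Kras tumours differs from normal lung. Kras tumours had more mRNA of most alveolar type 2 cell genes, of MHC class II genes and of several genes induced by RAS-ERK signalling, and less of most cardiac muscle genes and of some immediate early and matrix genes. Of 15824 genes tested, 488 rose and 336 fell, and 260 and 208 of these changed more than 2-fold. The groups did not overlap in 64.9% of genes, against 33.3% by chance. The counts depended on single libraries: edgeR called 0 genes without either Kras library, with 1682 and 2331 genes at an unadjusted p under 0.05. It called 0 higher and 3 lower without wild-type lung 2 (2655 at an unadjusted p under 0.05) and 116 higher without wild-type lung 1. Without mNSD2;Kras tumour 1 or 2 it called 1155 higher each time and 989 or 970 lower. With DESeq2 948 genes were higher and 1088 lower.

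Among called genes with at least 5 CPM in the higher group and no overlap between groups, the largest rises in Kras tumours included several developmental transcription factors. Of the genes named here, 0 were called by edgeR without Kras tumour 1, Kras tumour 2 or wild-type lung 2, and leaving out 1 library moved the fold of 13 of the 16 genes by more than 1.5 times. Btnl6, a butyrophilin-like gene (chromosome 17, 34507804 to 34517352), reached 7.56 ± 0.61 CPM (SD, n = 2) against 0 counts in wild-type lung, at least 49.6-fold higher. Hoxc13, a homeobox gene (chromosome 15, 102921103 to 102928814), reached 5.92 ± 0.59 CPM against 0 counts, at least 38.8-fold higher. The paired box gene Pax3 was 393-fold higher (95% counting interval 70.0 to 15548) and the homeobox gene Hoxd13 was 252-fold higher (44.7 to 9980), each against 1 count in wild-type lung. Nkx2-2, a homeobox gene of neural and islet development, rose by a log2 fold change of 7.62 ± 0.39 (adjusted p = 0.00843). Pax7, a regulator of muscle stem cells, was 40.5-fold higher, Cxcr1, a chemokine receptor, 35.1-fold, and Kng2, a kininogen gene, 21.4-fold. Leaving out 1 library gave log2 fold changes of 7.46 to 10.54 for Pax3, 4.59 to 7.06 for Pax7, 4.33 to 7.05 for Cxcr1 and 3.26 to 5.43 for Kng2. By the same rule the largest falls were in Bpifa1, an airway secretory gene (log2 fold change -6.27 ± 1.07, adjusted p = 0.0345), which measured 273 and 1741 CPM in wild-type lung and 17.9 and 8.21 CPM in Kras tumours. Nppa, a hormone of atrial heart muscle, was 25.3-fold lower. Tcap, a sarcomere gene, was 14.4-fold lower, but it measured 25.6 and 123 CPM in the wild-type libraries, and its log2 fold change was -2.30 without wild-type lung 2 (adjusted p = 0.0775). Retn, Plin1 and Thrsp, which fat cells express, were 16.9-fold, 14.8-fold and 14.6-fold lower, with log2 fold changes of -5.36 to -3.41, -5.91 to -3.07 and -4.50 to -3.02 when 1 library was left out. The calls of Kng2, Retn and Plin1 also ended without wild-type lung 1, and of 9 measured genes of the fat cell list 1 was called lower. Clec12b, a C-type lectin, was 23.3-fold lower and Bpifb1, a secretory gene of airways, 14.5-fold lower.

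Of the 15 alveolar type 2 cell genes, 12 rose in Kras tumours (13 when adjusted over the list alone) and 3 did not pass, with a median log2 fold change of 1.26 (camera adjusted p = 1.61e-22, and adjusted p = 0.25 with an estimated correlation). Lpcat1, an enzyme of surfactant lipid synthesis, rose by a log2 fold change of 1.59 ± 0.15. Cxcl15, a lung chemokine, was 4.88-fold higher, the surfactant protein gene Sftpd 2.10-fold and the aspartic protease Napsa 2.94-fold. All 8 MHC class II genes rose (8 when adjusted over the list alone), with a median of 1.19 (adjusted p = 2.58e-13, and adjusted p = 0.25 with an estimated correlation). H2-DMb1 and H2-DMa, which load peptides, were 2.41-fold and 2.22-fold higher, the antigen-presenting chain H2-Aa 2.19-fold and Ciita, the transactivator of the class, 2.04-fold. Of 12 MHC class I genes, 2 rose (11 when adjusted over the list alone), H2-D1 by 1.73-fold and H2-K1 by 1.85-fold, with a median of 0.43 (adjusted p = 6.16e-06, and adjusted p = 0.272 with an estimated correlation). The H2 genes resemble each other closely, so reads may be assigned to the wrong member. Of 14 epithelial junction genes, 5 rose (10 when adjusted over the list alone), among them the adhesion molecule Epcam (1.74-fold) and the transcription factor Grhl2 (1.68-fold), with a median of 0.53 (adjusted p = 6.16e-06, and adjusted p = 0.373 with an estimated correlation).

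Of 22 measured targets of RAS-ERK signalling, 7 rose in Kras tumours (7 when adjusted over the list alone) and 15 did not pass. The growth factor Areg was 4.28-fold higher, the ETS factors Etv4 and Etv5 10.3-fold and 2.31-fold, and the ERK phosphatase Dusp6 1.88-fold. The list's median was 0.22 (camera adjusted p = 0.000189, and adjusted p = 0.272 with an estimated correlation). Without Kras tumour 1, Kras tumour 2 or wild-type lung 2 that median was 0.12, 0.37 or 0.35. The longer list of genes raised by KRAS did not follow: of 178 measured members 8 rose and 12 fell (18 and 18 when adjusted over the list alone), with a median of -0.15 (adjusted p = 0.209, and adjusted p = 0.669 with an estimated correlation). Its strongest changes were a fall of Igfbp3, a binding protein of insulin-like growth factors (8.24-fold lower), and of Cpe, a carboxypeptidase of hormone processing (3.60-fold lower), and a rise of Hoxd11 from 0 counts in wild-type lung to 3.24 ± 0.54 CPM. Of 15 measured genes of progressed lung adenocarcinoma cells, 5 rose (7 when adjusted over the list alone), among them the tight junction gene Cldn2 (18.8-fold), the liver and gut regulator Hnf4a (10.5-fold), the transcription factor Onecut2 (26.8-fold) and the gastric protease Ctse (2.69-fold). With a term for sex the log2 fold changes were 3.43 for Onecut2 (4.75 without it), 3.32 for Cldn2 (4.23) and 3.999 for Etv4 (3.37). That term rests on the difference between the 2 mNSD2;Kras libraries. The adenocarcinoma list's median was 0.45 (adjusted p = 0.000143, and adjusted p = 0.25 with an estimated correlation), 0.07 without Kras tumour 1 and 0.20 without wild-type lung 1. Of 17 p53 targets and cell cycle inhibitors, 1 rose, the inhibitor Cdkn2a (12.7-fold), and 5 rose and 1 fell when adjusted over the list alone (median 0.21, adjusted p = 0.0122, and adjusted p = 0.506 with an estimated correlation). The call ended without wild-type lung 1 (adjusted p = 0.0629). Of the cell cycle lists, 0 genes passed (0 when adjusted over the list alone), but camera called both higher: 18 of 20 G1/S genes were positive, with a median of 0.37 (adjusted p = 0.00437, and adjusted p = 0.56 with an estimated correlation), and 16 of 20 G2/M genes, with a median of 0.36 (adjusted p = 0.0342, and adjusted p = 0.669 with an estimated correlation). The G2/M median was 0.16 without wild-type lung 2 (adjusted p = 0.244) and 0.57 without wild-type lung 1, and the call also ended without Kras tumour 1 (0.08).

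Genes of other cell types moved in both directions. Of 16 macrophage genes, 3 rose (4 when adjusted over the list alone): the scavenger receptor Marco (6.03-fold), the ribonuclease Ear2 (2.89-fold) and the pore-forming Mpeg1 (3.22-fold), with a median of 0.60 (adjusted p = 0.000285, and adjusted p = 0.451 with an estimated correlation). With a term for sex the log2 fold change of Mpeg1 was 0.95 (1.69 without it) and the call ended (adjusted p = 0.152). That term is the difference of mNSD2;Kras tumour 1 from tumour 2, which measured 1151 and 691 CPM of Mpeg1. Sex cannot be separated there from other differences between these 2 libraries. Of 10 cardiac muscle genes, 8 fell (10 when adjusted over the list alone), with a median of -2.07 (adjusted p = 1.03e-13, and adjusted p = 0.272 with an estimated correlation), among them the troponins Tnni3 (4.05-fold lower) and Tnnt2 (4.17-fold lower). Of 12 smooth muscle and pericyte genes, 1 fell (11 when adjusted over the list alone), the growth factor receptor Pdgfrb (1.84-fold lower), with a median of -0.98 (adjusted p = 1.28e-05, and adjusted p = 0.272 with an estimated correlation) that was -0.54 without wild-type lung 2. Of 14 fibroblast and matrix genes, 3 fell, Col1a1 (1.52-fold lower), Lum (6.90-fold lower) and Dcn (3.21-fold lower), while elastin, Eln, rose 1.84-fold. Without wild-type lung 2 the log2 fold change of Lum was -2.12 (-2.79 with it, adjusted p = 0.121). When adjusted over the list alone, 1 rose and 7 fell (median -0.56, adjusted p = 0.000971, and adjusted p = 0.25 with an estimated correlation). Among 14 immediate early and heat shock genes, which respond to tissue handling, 6 fell (10 when adjusted over the list alone), with Fosb 5.43-fold and Fos 4.14-fold lower and a median of -0.65 (adjusted p = 1.03e-07, and adjusted p = 0.25 with an estimated correlation). Of 16 genes of the unfolded protein and integrated stress responses, 2 rose (5 when adjusted over the list alone), the serine synthesis enzymes Psat1 (1.89-fold) and Phgdh (1.97-fold), with a median of 0.46 (adjusted p = 0.000118, and adjusted p = 0.272 with an estimated correlation). In all, camera called 14 lists higher and 7 lower of 33, of which 0 were called with an estimated correlation (adjusted p from 0.25 to 0.862), and fry called 10, 9 of them the same lists. The 17 endothelial genes had 0 called members and a median of -0.48 (adjusted p = 0.000971, and adjusted p = 0.56 with an estimated correlation), a list call that ended without Kras tumour 1 (0.0518) or wild-type lung 1 (0.0716). The 18 interferon-stimulated genes had 0 called members (5 lower when adjusted over the list alone) and a median of -0.43 (adjusted p = 0.0248, and adjusted p = 0.643 with an estimated correlation), -0.19 without wild-type lung 1 (adjusted p = 0.526), and this call also ended without Kras tumour 1 (0.067). Also called were the airway cell list (median -0.395, and -0.26 without wild-type lung 2) and, as higher, the cholesterol synthesis (0.39), NRF2 (0.31) and ribosomal protein lists (0.12, and 0.06 without wild-type lung 1). The airway call ended without wild-type lung 2, and the NRF2 and ribosomal protein calls ended without wild-type lung 1.

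The second comparison asked how mNSD2;Kras tumours differ from normal lung. Here 1675 genes rose and 1644 fell of 15824 tested, 698 and 886 of them more than 2-fold, and the groups did not overlap in 64.1% of genes against 33.3% by chance. Most alveolar type 2 cell, MHC and G1/S genes and some G2/M and macrophage genes rose, while the cardiac muscle and red blood cell genes and some endothelial and smooth muscle genes fell. Of the lists these belong to, 0 passed camera with an estimated correlation. Counts depended on single libraries. With only the compared groups fitted they were 520 and 508, against 1360 and 1451 in Kras tumours. They do not rank the tumour groups.

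By the rule used above, several of the genes with the largest rises were the same as in Kras tumours. Btnl6 (7.98 ± 0.20 CPM) was at least 52.3-fold higher and Hoxc13 (5.04 ± 1.74 CPM) at least 33.2-fold higher, each against 0 counts in wild-type lung. Hoxd13 was 260-fold higher (95% counting interval 46.3 to 10326) and Pax3 251-fold higher (44.5 to 9937), each against 1 count, and Nkx2-2 rose by a log2 fold change of 7.62 ± 0.39 (adjusted p = 0.00674). Awat1, an enzyme of wax ester synthesis, was 1118-fold higher (309 to 9238) and Cd200r2, an immune receptor, 133-fold higher (36.6 to 1108), each against 2 counts. Awat1 measured 108 CPM in mNSD2;Kras tumour 1 and 7.52 CPM in tumour 2, and Dmbt1, a secreted mucosal protein, 396 and 14.8 CPM (log2 fold change 7.15 ± 1.81, adjusted p = 0.0417). Among the largest falls were the fat cell genes Adipoq (1924-fold lower, 345 to 76040) and Retn (316-fold lower, 87.1 to 2613), Cfd (487-fold lower) and Car3 (1139-fold lower), and the gluconeogenic enzyme Pck1 (2191-fold lower, 393 to 86583). The others were the squamous keratin Krt13 and the muscle genes Ckm and Myl3, whose levels differed widely between the wild-type libraries: 5.27 and 2397 CPM for Krt13, 6.56 and 244 CPM for Ckm and 3.46 and 135 CPM for Myl3. Leaving out 1 library moved the fold of 13 of the 16 genes by more than 1.5 times, and Btnl6, Hoxc13, Hoxd13, Pax3, Nkx2-2, Adipoq and Retn stayed called each time. Without wild-type lung 2 the log2 fold change was -4.52 for Krt13, -3.87 for Ckm and -3.61 for Myl3, and without mNSD2;Kras tumour 1 it was 7.04 for Awat1 and 3.36 for Dmbt1. Awat1, Dmbt1 and Cd200r2 were not called without either Kras or either wild-type library, and Pck1, Cfd and Car3 not without mNSD2;Kras tumour 1 or either wild-type library.

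Of the 15 alveolar type 2 cell genes, 14 rose (14 when adjusted over the list alone), with Cxcl15 5.46-fold, Sftpd 2.87-fold, Lpcat1 2.74-fold and the mucin Muc1 2.56-fold higher and a median of 1.41 (camera adjusted p = 2.28e-15, and adjusted p = 0.273 with an estimated correlation). All 8 MHC class II genes rose (8 when adjusted over the list alone; median 1.42, adjusted p = 1.88e-10, and adjusted p = 0.273 with an estimated correlation), H2-Aa by 2.50-fold and H2-Ab1 by 2.87-fold. Of 12 MHC class I genes, 10 rose (11 when adjusted over the list alone), with H2-D1 2.32-fold higher and the peptide transporter Tap1 1.59-fold higher (median 0.63, adjusted p = 8.03e-07, and adjusted p = 0.273 with an estimated correlation). Of 14 epithelial junction genes, 7 rose and 1 fell (9 and 1 when adjusted over the list alone), with Epcam 1.89-fold higher (median 0.55, adjusted p = 6.73e-05, and adjusted p = 0.323 with an estimated correlation).

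Many cell cycle genes rose in mNSD2;Kras tumours against wild-type lung, where the medians of both lists were higher than in Kras tumours. Of 20 G2/M genes, 9 rose (17 when adjusted over the list alone), among them the mitotic kinase Cdk1 (3.01-fold, log2 1.59 ± 0.19), Cdc20 (2.14-fold) and the transcription factor Foxm1 (1.98-fold), with a median of 0.97 (adjusted p = 8.03e-07, and adjusted p = 0.342 with an estimated correlation). Of 20 G1/S genes, 14 rose (15 when adjusted over the list alone), among them Uhrf1 (2.51-fold), thymidine kinase Tk1 (2.25-fold) and the replication helicase genes Mcm5 (1.75-fold) and Mcm2 (1.68-fold), with a median of 0.74 (adjusted p = 8.03e-07, and adjusted p = 0.323 with an estimated correlation). Of 17 p53 targets and cell cycle inhibitors, 7 rose and 1 fell (8 and 1 when adjusted over the list alone), with Cdkn2a 23.4-fold, the pro-apoptotic Bax 1.84-fold and Zmat3 2.04-fold higher (median 0.51, adjusted p = 0.000101, and adjusted p = 0.307 with an estimated correlation). The p53 median was 0.32 without mNSD2;Kras tumour 1. Of 22 RAS-ERK targets, 7 rose and 1 fell (8 and 1 when adjusted over the list alone), with Areg 6.08-fold, Etv4 14.2-fold and cyclin D1, Ccnd1, 1.69-fold higher (median 0.31, adjusted p = 0.000597, and adjusted p = 0.307 with an estimated correlation). That median was 0.54 without wild-type lung 2. Of 178 genes raised by KRAS, 32 rose and 34 fell (37 and 39 when adjusted over the list alone), with a median of -0.06, a mean of 0.06 and adjusted p = 0.748 (adjusted p = 0.903 with an estimated correlation). That median was -0.23 without mNSD2;Kras tumour 1 and 0.004 without tumour 2. Of 15 genes of progressed lung adenocarcinoma cells, 7 rose (9 rose and 1 fell when adjusted over the list alone), with Cldn2 35.1-fold, Hnf4a 14.3-fold and Kng2 67.7-fold higher (log2 5.48 to 7.08 with either wild-type library left out; list median 1.33, adjusted p = 0.000101, and adjusted p = 0.273 with an estimated correlation).

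Some macrophage and inflammatory genes rose as well, and the size of the rise rested on one library. Of 16 macrophage genes, 7 rose (11 when adjusted over the list alone), with Marco 7.67-fold and the lysosomal Cd68 6.53-fold higher (a log2 fold change of 2.71, and of 1.85 without mNSD2;Kras tumour 1; list median 1.06, adjusted p = 1.09e-05, and adjusted p = 0.307 with an estimated correlation). Of 14 tumour-associated macrophage genes, 5 rose (9 when adjusted over the list alone; median 2.12, adjusted p = 0.000677, and adjusted p = 0.502 with an estimated correlation). The lipid receptor Trem2 measured 62.4 and 16.7 CPM, the glycoprotein Gpnmb 1091 and 212 CPM and the protease Ctsk 598 and 69.1 CPM in mNSD2;Kras tumours 1 and 2, against 2.87, 28.0 and 22.9 CPM on average in wild-type lung. Of 17 NF-kB targets and cytokines, 5 rose (10 when adjusted over the list alone), with Tnf 5.51-fold (log2 2.46, and 3.28 without wild-type lung 2), Csf2 3.25-fold and Nfkb2 1.63-fold higher (median 1.53, adjusted p = 5.04e-05, and adjusted p = 0.323 with an estimated correlation). Without mNSD2;Kras tumour 1 these 3 medians were 0.63, 0.62 and 0.63. Of 16 stress response genes, 7 rose (9 when adjusted over the list alone), with Psat1 2.56-fold and the chaperone cofactor Sdf2l1 2.92-fold higher (median 0.61, adjusted p = 0.000396, and adjusted p = 0.307 with an estimated correlation), and the median was 0.35 without mNSD2;Kras tumour 1.

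Part of the genes of vessels, muscle and blood fell in mNSD2;Kras tumours against wild-type lung. Of 17 endothelial genes, 7 fell (12 when adjusted over the list alone), with the angiopoietin receptor Tek 2.70-fold, the VEGF receptor Kdr 2.69-fold and the adhesion molecule Pecam1 1.65-fold lower (median -0.73, adjusted p = 1.94e-05, and adjusted p = 0.368 with an estimated correlation). Of 12 smooth muscle and pericyte genes, 7 fell (10 when adjusted over the list alone), with the smooth muscle myosin Myh11 2.79-fold lower (median -1.07, adjusted p = 1.94e-05, and adjusted p = 0.307 with an estimated correlation). All 10 cardiac muscle genes fell (10 when adjusted over the list alone), with Tnnt2 10.5-fold, Myl7 13.4-fold and the atrial myosin Myh6 16.5-fold lower (log2 -4.04, and -4.71 without mNSD2;Kras tumour 1; list median -3.53, adjusted p = 4.7e-15, and adjusted p = 0.295 with an estimated correlation). The 3 measured red blood cell genes fell (3 when adjusted over the list alone; median -2.72, adjusted p = 4.11e-05, and adjusted p = 0.273 with an estimated correlation): the haem synthesis enzyme Alas2 (6.44-fold lower), the anion exchanger Slc4a1 (7.86-fold lower) and glycophorin Gypa (6.60-fold lower). Haemoglobin genes were listed at 0 counts in all 10 libraries. Of 14 immediate early and heat shock genes, 5 fell and 1 rose (7 and 1 when adjusted over the list alone), with Jun 1.87-fold and Fosb 2.72-fold lower and the near-identical pair Hspa1a and Hspa1b 8.89-fold and 8.51-fold lower (median -0.85, adjusted p = 7.17e-05, and adjusted p = 0.273 with an estimated correlation). Of 14 fibroblast and matrix genes, 1 rose, Eln (4.07-fold), and 5 fell (1 and 8 when adjusted over the list alone; median -0.55, adjusted p = 0.0595, and adjusted p = 0.307 with an estimated correlation). The fibroblast list was called without mNSD2;Kras tumour 1 (adjusted p = 0.0182), Kras tumour 1 (0.0392), Kras tumour 2 (0.0372) or wild-type lung 2 (0.03). Camera called 16 lists higher and 7 lower of 33, of which 0 were called with an estimated correlation (adjusted p from 0.273 to 0.911), and fry called 16, 14 of them the same lists. Not named above were the airway cell (median -0.92, and -0.56 without mNSD2;Kras tumour 1) and mesothelial lists (-1.12), which were lower, and the cholesterol synthesis (0.48), NRF2 (0.58) and ribosomal protein lists (0.27), which were higher. The NRF2 call ended without wild-type lung 1.

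Both tumour groups were compared with the same 2 wild-type libraries, which by itself makes the fold changes alike. Of the 824 genes called in Kras tumours, 819 changed with the same sign in mNSD2;Kras tumours, 462 were called higher in both and 298 lower in both, and 0 were called in opposite directions. In 20 simulations without any group effect, the correlation of the fold changes across genes averaged 0.493 (0.459 to 0.514) from the shared libraries alone, against 0.867 measured, and 0.2 genes were called higher and 0.05 lower in both. Their covariance averaged 0.069 against 0.821 measured. Genes are not independent replicates, and with 2 wild-type libraries part of the excess cannot be separated from differences of those libraries. Of the 488 genes higher in Kras tumours, 275 had a larger fold change in mNSD2;Kras tumours, as did 203 of the 336 lower genes.

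The third comparison bears on whether mNSD2 adds to the expression program of Kras tumours. In edgeR 0 genes were called between mNSD2;Kras and Kras tumours, with 1996 genes at an unadjusted p under 0.05 (1101 higher, 895 lower) and a lowest adjusted p of 0.255. With limma-voom 0 were called, and with DESeq2 102 were higher and 91 lower. Without mNSD2;Kras tumour 2, which differed in sex from the other 3 tumour libraries, 679 genes were higher and 390 lower, and without mNSD2;Kras tumour 1 there were 3 and 4. The groups did not overlap in 45.8% of genes, against 33.3% by chance.

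Camera with its preset correlation called gene lists between the tumour groups although single genes did not pass. With an estimated correlation or with fry 0 lists were called, and an unchanged simulated list passed camera in this comparison, so these lists are described with that limit. All 20 G2/M genes had a positive log2 fold change (2 passed when adjusted over the list alone), with a median of 0.64 (camera adjusted p = 6.37e-10, and adjusted p = 0.489 with an estimated correlation). The proliferation marker Mki67 measured 58.8 and 35.0 CPM in mNSD2;Kras and 32.5 and 26.6 CPM in Kras tumours (log2 fold change 0.67 ± 0.27, adjusted p = 0.396). The topoisomerase Top2a measured 35.2 and 21.6 against 21.3 and 17.2 CPM (0.56 ± 0.28). Of 20 G1/S genes, 19 were positive (0 passed when adjusted over the list alone), with a median of 0.33 (adjusted p = 4.25e-07, and adjusted p = 0.489 with an estimated correlation). The 3 red blood cell genes were lower (3 when adjusted over the list alone), with a median of -2.51 (adjusted p = 1.49e-12, and adjusted p = 0.387 with an estimated correlation), and Alas2 measured 22.3 ± 7.17 CPM against 109 ± 26.8 CPM. All 10 cardiac muscle genes had a negative log2 fold change (5 passed when adjusted over the list alone; median -1.35, adjusted p = 2.16e-11, and adjusted p = 0.489 with an estimated correlation). Of 17 p53 targets, 14 were positive (5 passed when adjusted over the list alone; median 0.21, adjusted p = 0.000113, and adjusted p = 0.489 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 199 ± 10.2 against 135 ± 4.71 CPM. Of 18 interferon-stimulated genes, 14 were positive (0 passed when adjusted over the list alone; median 0.49, adjusted p = 0.000113, and adjusted p = 0.489 with an estimated correlation). Against wild-type lung this list was lower in Kras tumours (median -0.43) and had a median of -0.014 in mNSD2;Kras tumours (adjusted p = 0.748, and adjusted p = 0.911 with an estimated correlation; -0.16 to 0.25 with 1 library left out), so no rise over normal lung was called.

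Macrophage and inflammatory lists were also called higher by camera in mNSD2;Kras than in Kras tumours, mostly from one library. All 14 tumour-associated macrophage genes were positive (0 passed when adjusted over the list alone), with a median of 1.68 (adjusted p = 1.05e-07, and adjusted p = 0.489 with an estimated correlation). The secreted phosphoprotein Spp1 measured 2973 and 175 CPM in mNSD2;Kras tumours 1 and 2 and 161 and 218 CPM in Kras tumours (log2 fold change 3.06 ± 1.14, adjusted p = 0.387), and Gpnmb 1091 and 212 CPM against 210 and 153 CPM. That median was 0.16 (adjusted p = 0.0907) without mNSD2;Kras tumour 1 and was 2.31 without tumour 2. Of 16 macrophage genes, 15 were positive (0 passed when adjusted over the list alone; median 0.52, adjusted p = 0.000231, and adjusted p = 0.489 with an estimated correlation). Their median was 0.16 (adjusted p = 0.0939) without mNSD2;Kras tumour 1 and 0.85 without tumour 2. Of 17 NF-kB targets, 16 were positive (7 passed when adjusted over the list alone; median 0.88, adjusted p = 2.96e-08, and adjusted p = 0.489 with an estimated correlation). The NF-kB median was 0.27 without mNSD2;Kras tumour 1 and 0.57 without Kras tumour 2. The 15 T and NK cell genes were all positive (0 passed when adjusted over the list alone; median 0.54, adjusted p = 0.000763, and adjusted p = 0.489 with an estimated correlation). This median was 0.00 without mNSD2;Kras tumour 2 (adjusted p = 0.469) and 0.85 without tumour 1. The coreceptor Cd8a measured 9.31 and 18.2 against 8.14 and 7.20 CPM. Of 17 endothelial genes, 16 were negative (0 passed when adjusted over the list alone; median -0.29, adjusted p = 0.00149, and adjusted p = 0.611 with an estimated correlation). The endothelial call was lost without mNSD2;Kras tumour 1 (adjusted p = 0.2) or Kras tumour 2 (0.368), and the median was -0.55 without mNSD2;Kras tumour 2 and -0.51 without Kras tumour 1.

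The lists of RAS output were not called when all libraries were used. Of 22 RAS-ERK targets, 12 were positive and 10 negative (1 passed as higher when adjusted over the list alone), with a median of 0.11 (adjusted p = 0.412, and adjusted p = 0.742 with an estimated correlation) that was 0.032 without Kras tumour 2, 0.07 without mNSD2;Kras tumour 2 and 0.074 with the GC and length offset. Dusp6 measured 170 ± 19.5 CPM in mNSD2;Kras against 211 ± 0.41 CPM in Kras tumours. Of 178 genes raised by KRAS, 96 were positive (1 passed when adjusted over the list alone), with a median of 0.06 (adjusted p = 0.215, and adjusted p = 0.738 with an estimated correlation). This list was called higher without mNSD2;Kras tumour 2 (median 0.12, adjusted p = 0.00213), and its median was -0.019 without tumour 1. The alveolar type 2 cell list had a median of 0.04 (adjusted p = 0.363, and adjusted p = 0.827 with an estimated correlation), with the surfactant protein gene Sftpc at 25882 and 32405 CPM against 30274 and 25918 CPM. It was called higher without Kras tumour 1 (median 0.17, adjusted p = 0.0217), and its median was -0.076 without Kras tumour 2. Camera called 14 lists higher and 5 lower of 33 in this comparison, of which 0 were called with an estimated correlation (adjusted p from 0.387 to 0.989), and fry called 0. Not named above were the airway cell (median -0.29) and mesothelial lists (-0.63), which were lower, and the glycolysis and hypoxia (0.435), progressed adenocarcinoma (0.38), mesenchymal transition (0.29), NRF2 (0.23), MHC class I (0.22) and ribosomal protein lists (0.14), which were higher. Without mNSD2;Kras tumour 1 the airway, glycolysis, adenocarcinoma and NRF2 medians were -0.043, 0.081, 0.13 and 0.087 and these calls ended. Without mNSD2;Kras tumour 2 the MHC class I and ribosomal protein calls ended. The mesothelial median was -0.20 without Kras tumour 2 (adjusted p = 0.432), and the mesenchymal one was 0.12 without mNSD2;Kras tumour 1.

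**Figure D2:**
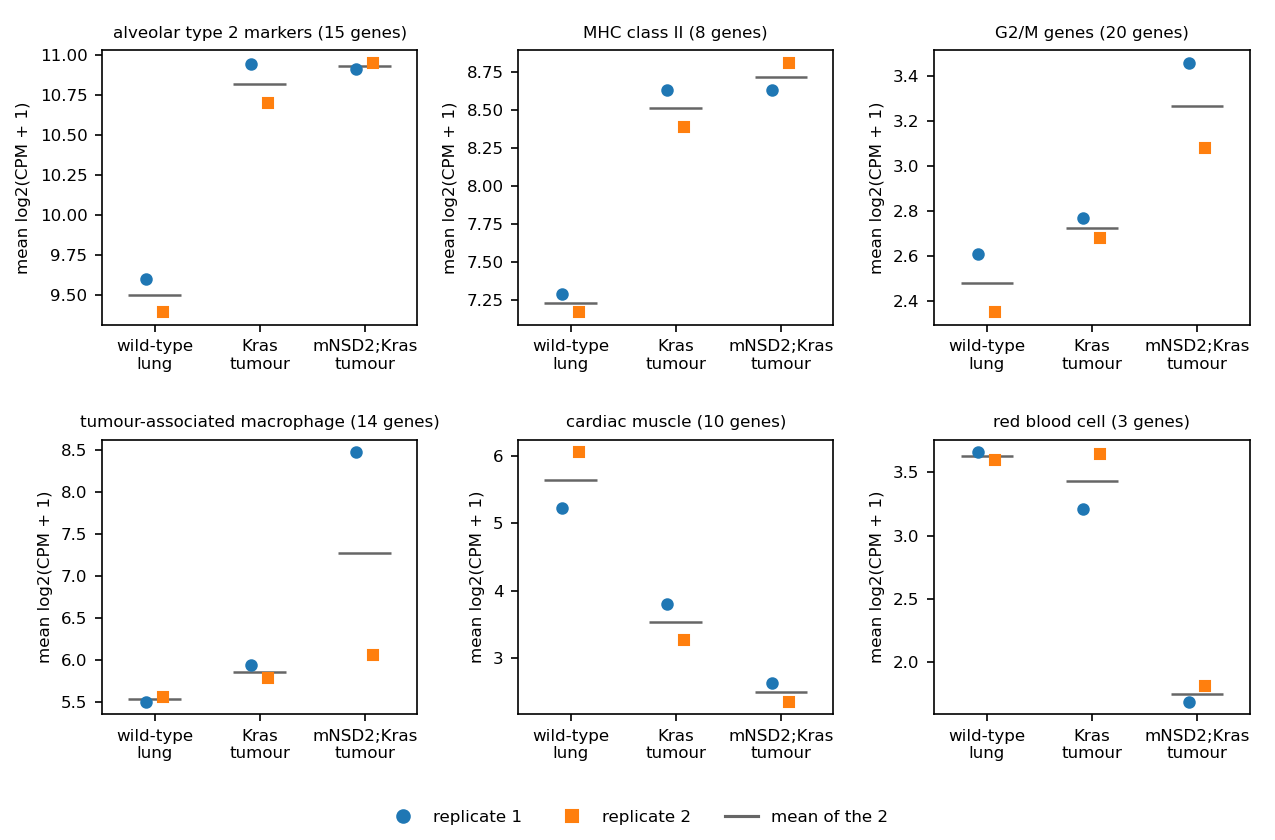
Mean log2(CPM + 1) of 6 gene lists (vertical axes, each with its own range) in the 3 tissue groups (horizontal axes), with circles for replicate 1, squares for replicate 2 and lines for their mean. The tumour-associated macrophage list stands at 8.47 in mNSD2;Kras tumour 1 and at 6.06 in tumour 2, while the red blood cell list stands at 1.69 and 1.81 in mNSD2;Kras tumours and at 3.21 or more in the other 4 libraries.

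The fourth comparison asked how primary mNSD2;Kras tumour cells labelled sgNSD2 differ from those labelled sgControl. Of 12264 genes tested, 81 were higher and 43 lower, all by more than 2-fold, and 2579 had an unadjusted p under 0.05 (1270 higher, 1309 lower). The groups did not overlap in 56.2% of genes, against 33.3% by chance. The counts of called genes were 3598 higher and 3395 lower without sgControl 1, 1391 and 1035 without sgControl 2, 15 and 2 without sgNSD2 1, and 98 and 3 without sgNSD2 2. Higher genes made up 65.3% of the called genes with TMM and 76.8% (53 higher, 16 lower) with upper-quartile factors, which move the median log2 fold change of all genes by 0.116 relative to TMM. The balance turned with DESeq2 (233 higher, 494 lower), with the GC and length offset (761 and 918) and with all 10 libraries in the fit (743 and 913), so no direction is drawn from it.

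By the rule used above, the largest rise in cells labelled sgNSD2 was in B4galnt2, a glycosyltransferase (chromosome 11, 95865943 to 95914891), which measured 5.35 ± 0.28 CPM against 0.247 ± 0.003 CPM (log2 fold change 4.40 ± 0.55, n = 2 per group, adjusted p = 0.00952). The apolipoprotein Apoa1 was 14.8-fold higher, and the inter-alpha-trypsin inhibitor heavy chains Itih5 and Itih2 were 14.8-fold and 14.6-fold higher. Greb1, a gene induced by oestrogen, was 18.4-fold higher, Firre, a noncoding RNA of the X chromosome, 11.7-fold, the ankyrin repeat gene Ankrd23 10.1-fold and the matrix proteoglycan Bgn 9.79-fold. Among called genes with at least 5 CPM in the higher group and no overlap between groups, the largest fall was in Gpnmb (chromosome 6, 49036546 to 49070929), which measured 0.989 ± 0.005 CPM against 11.4 ± 3.64 CPM (log2 fold change -3.52 ± 0.48, adjusted p = 0.0135). The squamous differentiation genes Sprr1b, Lor and Krt6b were 10.9-fold, 6.84-fold and 6.47-fold lower. The thyroid hormone transporter Slc16a2 was 7.20-fold lower and the neuropeptide precursor Vgf 6.57-fold lower. The histone genes H2ac7 and H2ac8 were 10.3-fold and 7.99-fold lower, but their copies are nearly identical, so the member concerned is uncertain. B4galnt2, Greb1, Apoa1, Itih5, Itih2 and Firre stayed called with any library left out. Without sgNSD2 1 the calls of Ankrd23, Bgn and the 8 genes with the largest falls ended, and without sgNSD2 2 those of 7 of these 8, all but H2ac7. The fold moved by more than 1.5 times for Ankrd23 (2.45 on the log2 scale without sgNSD2 1), Bgn (2.63), Apoa1 (4.505 without sgControl 2), and H2ac7 and Lor (-2.65 and -2.18 without sgControl 2, and -2.75 and -2.085 with the GC and length offset).

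**Figure D3:**
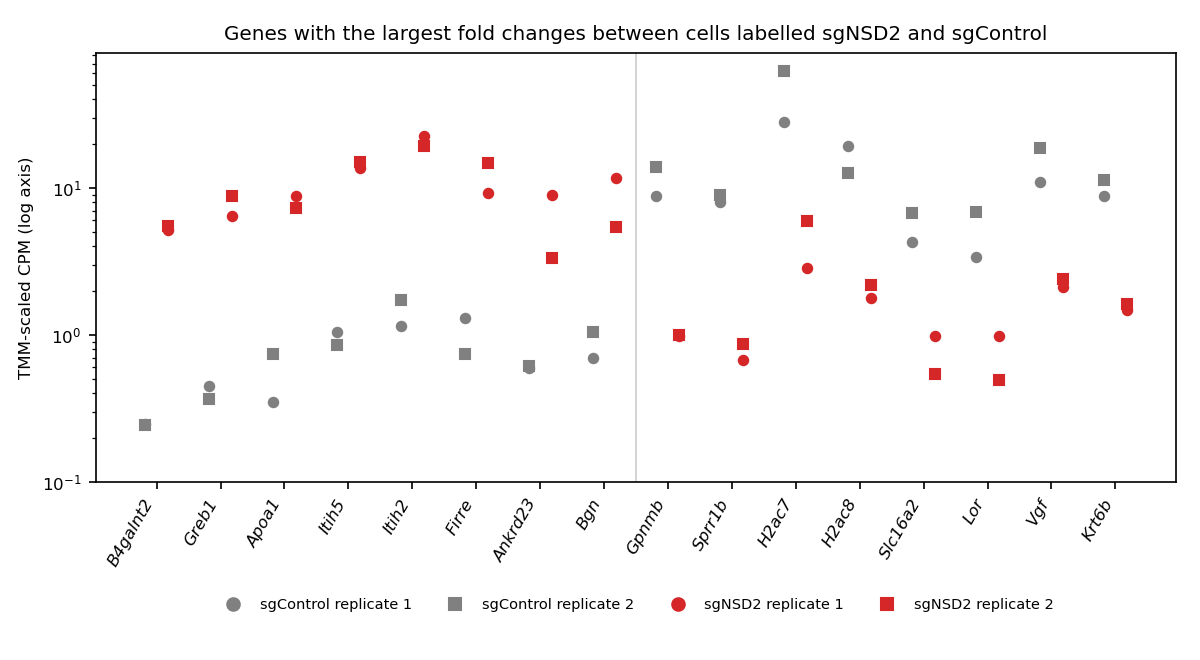
TMM-scaled CPM (log axis) of 16 genes in cells labelled sgNSD2 (red) and sgControl (grey), the 8 largest rises and 8 largest falls among called genes with at least 5 CPM in the higher group and no overlap between groups, with circles for replicate 1 and squares for replicate 2. Itih2 stands at 22.4 and 19.3 CPM in the cells labelled sgNSD2 against 1.15 and 1.72 CPM in sgControl cells, and Gpnmb at 0.986 and 0.992 against 8.81 and 14.0 CPM.

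Few of the gene lists differed between the cells. Of 3 measured replication-dependent histone genes, 1 fell, H2ac8 (3 when adjusted over the list alone), with a median of -2.77 (camera adjusted p = 0.000335, and adjusted p = 0.77 with an estimated correlation). The histone call ended without sgControl 1 (adjusted p = 0.326). Of 14 immediate early genes, 2 fell (4 when adjusted over the list alone), Fosb (log2 fold change -2.19 ± 0.41) and the stress factor Atf3 (-2.16 ± 0.43), with a median of -0.47 (adjusted p = 0.000734, and adjusted p = 0.77 with an estimated correlation). Without sgControl 1 the median was -0.75 and the call ended (adjusted p = 0.0572). The calls of Fosb and Atf3 ended under some alternatives, with log2 fold changes of -2.62 to -1.76 and of -2.36 to -1.99 over them. Of 13 NRF2 targets, 0 passed over all genes (5 higher and 1 lower when adjusted over the list alone), with a median of 0.71 (adjusted p = 0.0333, and adjusted p = 0.77 with an estimated correlation). This call ended without sgControl 1 (adjusted p = 0.0943) or sgNSD2 1 (0.158), and the median was 0.33 without sgControl 2 and 0.42 with the GC and length offset. Malic enzyme, Me1, measured 127 ± 1.06 CPM against 62.0 ± 12.1 CPM. Of 16 cholesterol synthesis genes, 0 passed over all genes (2 higher when adjusted over the list alone), with a median of 0.53 (adjusted p = 0.0209, and adjusted p = 0.77 with an estimated correlation). The cholesterol call ended without sgControl 1 (adjusted p = 0.239) or sgNSD2 1 (0.0802). Of 30 ribosomal protein genes, 0 passed (0 when adjusted over the list alone), with a median of -0.32 (adjusted p = 0.0333, and adjusted p = 0.856 with an estimated correlation). The ribosomal call ended without sgNSD2 2 (adjusted p = 0.332) and with the GC and length offset (median -0.17, adjusted p = 0.229), and the median was -0.19 with upper-quartile factors. Without sgControl 1, sgControl 2, sgNSD2 1 and sgNSD2 2, that median was -0.58, -0.13, -0.52 and -0.14. Of 8 cardiac muscle genes, 0 passed over all genes (6 higher when adjusted over the list alone), with a median of 3.26 (adjusted p = 0.0487, and adjusted p = 0.77 with an estimated correlation) and of -0.53 without sgNSD2 1 (adjusted p = 0.415). The cardiac call also ended with upper-quartile factors (adjusted p = 0.0979) and with the GC and length offset (0.154), although the medians there were 3.37 and 3.25. Cardiac transcripts stood far higher in sgNSD2 1 than in sgNSD2 2, with Actc1 at 75.5 against 1.61 CPM and Myh6 at 74.0 against 1.74 CPM.

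RAS-related and cell cycle lists were not called in the cells by the test used throughout. Of 23 RAS-ERK targets, 0 passed (0 when adjusted over the list alone), with a median of 0.29 (adjusted p = 0.804, and adjusted p = 0.901 with an estimated correlation), which was 0.09 without sgControl 2 and 0.18 with the GC and length offset. Of 131 genes raised by KRAS, 4 rose and 3 fell (16 and 7 when adjusted over the list alone), with a median of 0.33 (adjusted p = 0.0519, and adjusted p = 0.77 with an estimated correlation). Among these, the retinoic acid synthesis enzyme Aldh1a3 was 5.60-fold higher and the transcription factor Mycn 7.28-fold higher, and Slpi, a protease inhibitor of mucosa, was 14.2-fold lower (log2 -3.82, and -4.65 without sgNSD2 1, where the call ended). Of 17 genes of progressed lung adenocarcinoma cells, 2 rose (2 rose and 1 fell when adjusted over the list alone), the gastric genes Ctse (9.20-fold) and Tff2 (6.37-fold), with a median of 0.23 (adjusted p = 0.123, and adjusted p = 0.77 with an estimated correlation). The G1/S list had a median of -0.18 (adjusted p = 0.327, and adjusted p = 0.77 with an estimated correlation) and the G2/M list of -0.06 (adjusted p = 0.804, and adjusted p = 0.901 with an estimated correlation). Without sgControl 2, 3 of these lists were called: the genes raised by KRAS (median 0.23, and 0.49 without sgControl 1, adjusted p = 0.036), the progressed adenocarcinoma genes (0.37, adjusted p = 0.0342) and the G2/M list (-0.205, adjusted p = 0.036). The G1/S median was -0.32 without sgControl 1, -0.36 with the GC and length offset (adjusted p = 0.0907), -0.28 with DESeq2 size factors and -0.057 with upper-quartile factors. With the offset the median of the genes raised by KRAS was 0.14. The adenocarcinoma median was 0.12 with DESeq2 size factors and 0.35 with upper-quartile factors. The G2/M median was 0.21 without sgControl 1, 0.04 with upper-quartile factors and -0.15 with the offset, and fry called the progressed adenocarcinoma genes (adjusted p = 0.023). Camera called 3 lists higher and 3 lower of 29, of which 0 were called with an estimated correlation (adjusted p from 0.77 to 0.916), and fry called 6, 3 of them the same lists.

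The last comparison asked whether genes that stood apart between the tumour groups moved the opposite way in cells labelled sgNSD2. It took the 200 genes ranked highest and the 200 ranked lowest between mNSD2;Kras and Kras tumours and tested them as sets in the cells, with p values adjusted over the 2 sets, an adjustment chosen after the results were seen. The higher set had a median log2 fold change of -0.32 in cells labelled sgNSD2 against sgControl (camera adjusted p = 0.00108), and 63 of its genes were positive. The lower set had a median of 0.31 (camera adjusted p = 0.00108), and 143 of its genes were positive. The median of all 11939 genes measured in both fits was 0.09. Neither set passed with an estimated correlation (adjusted p = 0.494 for each) or with fry (adjusted p = 0.381 for each). Of the higher set, 2 genes were called higher and 3 lower in the cells, and of the lower set 5 and 1. The higher set's call ended without sgControl 2 (median -0.05, adjusted p = 0.278), without mNSD2;Kras tumour 2 (-0.06, adjusted p = 0.322) and with the GC and length offset (-0.08, adjusted p = 0.519), and its median was -0.56 without sgControl 1. The lower set's call ended without sgControl 2 (median 0.13, adjusted p = 0.0813). Its median was 0.19 without sgNSD2 2, 0.67 without sgControl 1 and 0.12 with the offset (adjusted p = 0.0433). Since no fall of Nsd2 mRNA was called under the sgNSD2 label, the direction is that of the labels alone.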

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

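The alternatives chosen only after the results were seen were the newer quasi-likelihood option, the GC and length offset, the term for sex, leaving out X- and Y-linked genes, crossed pairing, leaving out cardiac and related genes, and upper-quartile factors for the lists. Unless a cause is named, the cause of a change was not tested.

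In Kras tumours against wild-type lung, where 488 genes were higher and 336 lower, DESeq2 called 948 and 1088, a fit of the 2 groups alone 1360 and 1451, and a fit of all 10 libraries 157 and 93. The replicate block left 194 lower, and the term for sex gave 252 higher and 226 lower, of which 153 and 45 had been called without it. The test against a log2 fold change of 1 left 6 and 1. In mNSD2;Kras tumours against wild-type lung (1675 and 1644), the fit of 2 groups called 520 and 508, the fit of all 10 libraries 687 and 723, and the test against 1 called 46 and 48. Between the tumour groups, where edgeR called 0 genes, DESeq2 called 102 and 91 and the term for sex gave 896 and 558. That term rests on the 2 mNSD2;Kras libraries alone, which differ in sex. Between the tumour groups, the fold changes with it are therefore those of mNSD2;Kras tumour 1 against the Kras tumours. These counts give no estimate of an effect of mNSD2 freed of sex.

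In the cells, where 81 genes were higher and 43 lower, DESeq2 size factors gave 37 and 25, upper-quartile factors 53 and 16, no filter 540 and 540, DESeq2 233 and 494, and the fit of all 10 libraries 743 and 913. The test against 1 left 6 and 0 (2579 genes passed an unadjusted p under 0.05 in the test against 0), and the newer quasi-likelihood option gave 136 and 104. The GC and length offset gave 761 and 918. Counts followed transcript GC content with a correlation of 0.68 in sgControl 2, against -0.40 in sgControl 1, -0.22 in sgNSD2 1 and -0.51 in sgNSD2 2, so the sgControl libraries differ in a trend that the offset removes. Leaving out the cardiac and related genes gave 77 lower. Counts under the alternatives not listed here stayed within 1.5 times those of the report.

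Leaving out 1 library gave 0 to 1155 genes higher and 0 to 989 lower in Kras tumours against wild-type lung, 148 to 2461 and 226 to 2182 in mNSD2;Kras tumours against wild-type lung, 0 to 679 and 0 to 390 between the tumour groups, and 15 to 3598 and 2 to 3395 in the cells. A group left with 1 library was assumed to vary like the other groups.

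The titles of the sgControl libraries carry the tags NSD2EK1 and NSD2EK2 while both file names carry EK1, so which culture each replicate number stands for is uncertain in the cells. No label says whether the replicate numbers pair the libraries. The correlation of replicate differences between groups was -0.05, -0.05 and 0.17 in the tissues and -0.43 in the cells. These values do not settle the pairing, and in the cells the replicate differences also carry the GC trends given above. With replicate number as a block, the counts were 327 and 194, 1437 and 1498, 0 and 0, and 80 and 40 in the order of the comparisons. With the block the list of genes raised by KRAS was called higher in the cells (median 0.37, adjusted p = 0.0418, from 0.036 to 0.77 over its alternatives), and the median of the cardiac list was 1.84 (adjusted p = 0.00136). The opposite pairing of the cell libraries gave 926 and 790, far more than the numbered pairing, and no label supports it.

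For the genes ranked by the difference between tumour groups, the sets kept their direction in the cells under all alternatives run. The higher set had a median of -0.32 with an estimated correlation and with fry, neither of which passed, and of -0.076 with the GC and length offset, with the preset or the estimated correlation (adjusted p over its alternatives from 9.2e-06 to 0.819). The lower set had 0.31 with an estimated correlation and with fry, and 0.12 with the offset and an estimated correlation, none of which passed (adjusted p from 8.38e-05 to 0.494). Leaving out 1 library gave medians of -0.56 to -0.05 and of 0.13 to 0.67.

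Named genes that were called in the report kept their direction in all 4521 values under the alternatives, of which 1063 lost the call. For named genes that were not called, 6005 of 6576 values kept direction and side of the threshold, 268 changed sign without a call, 301 gained a call in the same direction and 2 were called in the opposite one. Spp1 in Kras tumours against wild-type lung had a log2 fold change of -3.55 with the term for sex, and Abca3 in the cells one of 0.55 without sgControl 2. That term takes up the difference of Spp1 between mNSD2;Kras tumours 1 and 2 (2973 and 175 CPM). Of 1478 values of gene lists, 1237 kept both, 44 changed sign without a call, 156 lost the call, 38 gained it and 3 reversed. These 3 were the neutrophil and cholesterol lists between the tumour groups without mNSD2;Kras tumour 1 (medians -0.28 and -0.19, against 0.14 and 0.29 without tumour 2) and the cardiac list in the cells without sgNSD2 1 (-0.53, against 4.16 without sgNSD2 2).

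In simulation, small changes were often missed. On simulated data with the same depth and spread, 40%, 27%, 35% and 12% of changes of 1 on the log2 scale were found in the 4 comparisons, against 84%, 81%, 81% and 72% of changes of 2, so a gene that was not called may still have changed about 2-fold.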

Other observations

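The developmental transcription factor families, the lists of squamous, skeletal muscle and fat cell genes, the tests of poly(A) tails and S phase for the histone genes, both tests on macrophage genes, the term for sex and the test of sex on separate wild-type libraries were chosen only after the results were seen.

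Members of the Hox, Pax, Nkx, Dlx, Lhx and sine oculis homeobox families of developmental transcription factors were frequent among the genes higher in tumours than in wild-type lung. Of 40 tested members, 11 were called higher in Kras tumours (Hoxc10, Hoxc13, Hoxd8, Hoxd10, Hoxd11, Hoxd13, Nkx2-1, Nkx2-2, Pax2, Pax3 and Pax7), or 27.5% against 3.02% of other genes. In mNSD2;Kras tumours 14 were called higher, the same 11 with Hoxd9, Lhx2 and Six2 (35% against 10.5%). Called lower were 1 in Kras tumours, Hoxb3, and 5 in mNSD2;Kras tumours, Hoxb2, Hoxb3, Hoxb4, Hoxc5 and Six1. Of 27 members tested in the cells, 0 were called by edgeR. Without either Kras library edgeR called 0 genes in Kras tumours (1682 and 2331 at an unadjusted p under 0.05), these included. The families were chosen because members stood among the largest rises, so these shares carry no test, and both comparisons used the same wild-type libraries.

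The enzymes of H3K36 and H3K27 methylation changed little. Of 17 measured, 1 rose in Kras tumours against wild-type lung, Nsd2 (1 rose and 1 fell when adjusted over the list alone; median -0.06, camera adjusted p = 0.587, and adjusted p = 0.778 with an estimated correlation). In mNSD2;Kras tumours 1 rose, Nsd2, and 1 fell, Ash1l (1 and 0 when adjusted over the list alone; median -0.07, adjusted p = 0.655, and adjusted p = 0.829 with an estimated correlation). Between the tumour groups edgeR called 0 (0 when adjusted over the list alone; median 0.00, adjusted p = 0.987, and adjusted p = 0.989 with an estimated correlation). In the cells 0 passed, and 16 were positive (0 when adjusted over the list alone; median 0.15, adjusted p = 0.41, and adjusted p = 0.879 with an estimated correlation). Leaving out 1 library gave medians of -0.072 to 0.011, -0.142 to 0.004, -0.056 to 0.024 and, in the cells, 0.069 (without sgNSD2 2) to 0.348 (without sgControl 1), and 0 of these list tests passed. With the GC and length offset they were 0.08, 0.09, 0.021 and 0.032. The list of cholesterol synthesis genes was called higher in both tumour groups against wild-type lung. In Kras tumours 0 of 16 genes passed (0 when adjusted over the list alone), 15 were positive and the median was 0.39 (adjusted p = 0.000285, and adjusted p = 0.56 with an estimated correlation), with 0.33 to 0.41 when 1 library was left out. In mNSD2;Kras tumours against wild-type lung, 6 of 16 cholesterol synthesis genes rose (7 when adjusted over the list alone), with Dhcr7 2.36-fold higher (median 0.48, adjusted p = 0.000373, and adjusted p = 0.502 with an estimated correlation), and the median was 0.20 without mNSD2;Kras tumour 1.

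Some libraries held transcripts of other tissues. The mean log2(CPM + 1) of squamous genes was 6.49 in wild-type lung 2 and 0.83 in wild-type lung 1, that of skeletal muscle genes 7.67 and 1.27, and that of fat cell genes 4.36 and 6.0. The cardiac muscle list stood at 3.87 in sgNSD2 1 and at 1.34 to 1.68 in the other cell libraries. Of the 336 genes lower in Kras tumours than in wild-type lung, 12 differed more than 2-fold between the wild-type libraries, as did 3.52% of all genes above 1 CPM. Calling favours genes whose replicates agree, and the cardiac muscle list stood at 5.22 and 6.05 in wild-type lung 1 and 2. The count of 12 therefore does not show how many falls come from transcripts of other tissues. No explanation was tested for the levels of these lists. On the X and Y chromosomes lay 34 of the genes called in Kras tumours and 112 of those called in mNSD2;Kras tumours against wild-type lung, and 5 of those called in the cells.

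Replication-dependent histone genes were lower in cells labelled sgNSD2: 22 of 24 tested had a negative log2 fold change with TMM, DESeq2 size factors and upper-quartile factors, 6 were called lower, and the median was -2.04. Without sgNSD2 1 or without sgNSD2 2 not all of these calls held, although the medians were -2.06 and -2.08. Fewer cells in S phase would lower replication genes too. The G1/S list fell less: its lower quartile was -0.52 (median -0.18). It was -0.49 after an offset for GC content and length (median -0.36) and -0.77 without sgControl 1 (-0.32), the lowest value compared. How far S phase would lower each list is unknown, so it stays open. After that offset the median of the 23 histone genes with a GC value was still -1.75 (-2.07 without it, interquartile range 1.36). This argues against the GC trend as the whole cause. Recovery of RNA without a poly(A) tail cannot be told apart from a change in histone transcripts: Rn45s, the rRNA precursor, had a log2 fold change of -1.83 ± 0.42 that missed the threshold (adjusted p = 0.0662), with 2914 and 3736 CPM in sgNSD2 against 9922 and 13745 CPM in sgControl cells. Nuclear RNAs that in part lack a poly(A) tail did not follow it: Malat1 measured 18.9 and 26.6 against 11.6 and 3.43 CPM and Neat1 42.3 and 63.6 against 9.61 and 10.5 CPM. They cannot decide the question, since they lack a tail only in part. The list of small RNAs without a tail, at a mean log2(CPM + 1) of 0.29 and 0.33 against 0.32 and 0.37, lay too low to decide. Whether the class as a whole was lower is therefore left open. Reads shared among the nearly identical histone copies and an effect of the guide against Nsd2 stay open and untested.

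Macrophage genes were higher in mNSD2;Kras tumour 1 than in tumour 2, with median log2 ratios of 1.87 over the 14 tumour-associated genes and 0.89 over the 16 general genes. More macrophages of every kind would raise both lists alike, but the medians' ratio was 0.47, and the general upper quartile, 1.26, lay below the other median. Sex would place tumour 1 with the Kras tumours, which also held Y-linked transcripts, but tumour 1 exceeded their mean by a median of 2.32 (interquartile range 1.28). In the cells the lists stood at 3.66 to 4.11 (tumour-associated) and 0.54 to 0.67. Tumour cells or changed macrophages may explain the pattern (untested). With 1 library showing it, no link to mNSD2 can be drawn.

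Sex differed completely between wild-type lung and Kras tumours, so it could have produced the genes called between them. The mNSD2;Kras tumours differ in sex from each other, and over the 2811 genes called in a fit without them they differed by a median of only 0.15 in the called direction (interquartile range 0.61), against a median called change of 0.72. With 500 genes chosen from Kras tumours and 1 wild-type library, mNSD2;Kras tumour 2, in which Xist was detected as in wild-type lung, still differed from the other wild-type library in the chosen direction for 95.8% and 88.6% of them, with a lower quartile of at least 0.542. This argues against sex as the whole cause. With a term for sex, 153 of the 488 higher and 45 of the 336 lower genes were still called. Over all, median log2 fold changes were 1.01 and -1.09 (1.08 and -1.17 without it). The term rests on the 2 mNSD2;Kras libraries, and calling favoured genes alike in both (median difference 0.012, against 0.15 above). The medians exclude no share of sex.

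Whether genes raised in Kras tumours rose further in mNSD2;Kras tumours was tested with the 200 genes highest in 1 Kras library and the other Kras library as reference. The median log2 ratio was 0.26 against Kras tumour 2 and -0.04 against Kras tumour 1, at percentiles 100 and 1.54 of 10000 random lists. The 2 medians went opposite ways, so a further rise cannot be told apart from the difference between the 2 Kras libraries.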
